A study of Mus musculus with 8 samples.

How the data were processed

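RNA from 8 mouse livers was sequenced, 4 labelled wild type (WT) and 4 labelled Triple LKO. LKO stands for liver-specific knockout, and the 3 genes are those of the tristetraprolin (TTP) family, Zfp36, Zfp36l1 and Zfp36l2, whose products bind AU-rich sequences in the 3′ untranslated region (3′ UTR) of mRNAs and promote their decay. Each genotype holds 2 females and 2 males, as the labels give genotype and sex for every sample. Replicate numbers follow the order of the samples and pair nothing across groups. Sample titles hold running numbers, and each LKO-labelled liver has a WT liver of its sex with a number 1 to 5 away, so a fit blocked on these pairs was tried after the data were seen. Deviations from the mean of each genotype and sex correlated by 0.131 within the female and 0.15 within the male pairs. With 2 livers per mean these are 1 value per sex, and no label says what neighbouring numbers share, so the block stayed an alternative. The labels do not say which parts of a liver were taken, the age of the animals, or whether tissue came from a tumour. They also do not say in so many words that the 8 samples are 8 animals, so p-values measure the spread between these samples.

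The deposited table holds FPKM values, fragments per kilobase of transcript, scaled to the fragments of each library, for 35275 gene identifiers, with 1 column per sample. Per the submitters' processing notes, fastp, STAR 2.6.1, HTSeq and DESeq2 were used with the mm10 mouse genome; their roles, parameters and strand setting are not given in the sources used here, and neither is the annotation release. Where strand is not stated, reads of overlapping or antisense genes cannot be told apart. The deposited FPKM values of each library were whole multiples of what 1 fragment is worth for the gene, 100.0% of values to within 0.001 of a fragment, which gave back the depth of each library and the fragments per gene. Depth ranged from 15.1 to 18.8 M fragments. The recovered fragments summed to between 100.171% and 100.373% of that depth, so single genes may be off where an inferred length was a multiple of the true one, and the lengths equalled the longest annotated transcript for 63.4% of genes with a mean FPKM above 5. Shares of fragments carry 95% Wilson intervals of at most ±0.0239 percentage points, and a gene listed at 0 may have up to 3 fragments; both cover counting error only. An FPKM divides by the total of all genes, so a library in which a few genes take a smaller share shows higher values for the rest.

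Symbols were found for 34490 of the 35275 identifiers, and 785 had none. Coordinates are 1-based, on the GRCm38 (mm10) assembly, from the GENCODE M21 annotation. Of all identifiers, 12532 had a value of 0 in every library. Genes with a mean FPKM of at least 0.5 over the 8 libraries were tested, 13573 in number, on the scale log2(FPKM + 1). A fold on that scale understates the change of genes with low values. The main test was limma-trend (limma 3.58.1, R 4.3.3) with genotype and sex as terms and Benjamini-Hochberg adjusted p under 0.05 as the threshold. The within-sex genotype effects, the sex differences and the genotype-by-sex interaction came from a limma model with 1 mean per genotype and sex. That model has 4 residual degrees of freedom, and every contrast of 2 against 2 livers borrows its spread from all 8 libraries. The LKO-labelled females varied more than the other groups, as given below. Counts within females and within males, of genes and of list members, are thus not a like comparison. A count test was not the main test, since the values are FPKM. The targeted genes were also put to a two-sided exact permutation test over the 70 ways to choose 4 of 8 libraries, which cannot give a p below 0.0286, and over the 36 ways that keep 2 females and 2 males on each side, which cannot give one below 0.0556.

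Before the data were examined, 40 gene lists of pathways and cell types and 28 single genes were fixed from textbook knowledge of liver, together with the model, the alternatives and the rule for naming genes. Lists with at least 5 tested members, 38 of them, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera compares a list with all other genes. Camera with an estimated correlation and fry were run beside it; fry tests whether a list's genes move, on balance, in the same direction and does not compare them with other genes. The list of targeted genes (3 tested members) and that of pancreas acinar cells (3 of 13 members tested) were too short. Genes named for the genotype effect are the targeted genes, the 28 fixed genes, the 12 with the largest rise and the 12 with the largest fall among protein-coding genes past the threshold with a mean FPKM of at least 1 and no overlap between the genotypes, and up to 4 members of each list with the smallest p, of which the first are named, leaving out symbols that are identifiers or predicted genes. For the interaction, the 6 genes with the smallest p are named. For each sex difference, the 5 largest in each direction are named, with up to 3 members of each sex-biased list. Names chosen after their values were seen are marked as such. A few genes that these rules would name are not reported here, though counts of genes and lists include them. Mup, Cyp2c, Cyp2d, Cyp4a, Sult2a, Serpina1, Saa and immunoglobulin genes have near-identical copies, and the counting could split reads between them, so their single values are uncertain.

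For the 3′ UTR test, the longest annotated 3′ UTR of each gene was searched for the heptamer TATTTAT, and the median log2 change of genes with at least 3 copies was set against 10000 random lists matched on 3′ UTR length and mean expression. Of the tested genes, 12291 had an annotated 3′ UTR. For the autosome test, each library's log2 values were set against the mean of the WT libraries, leaving out the library itself, for 9983 autosomal genes with a mean FPKM of at least 2. The spread of the 19 chromosome medians was compared with 10000 shuffles of the genes. The genes of each chromosome were also divided at their median start position into a first and a second part, and the medians of both parts were correlated over the 19 chromosomes with 100000 permutations.

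The tests were tried on counts simulated from each gene's mean in the WT libraries and the real depths. All genes and groups had 1 dispersion, 0.054, the median over genes of that within genotype and sex. The real LKO-labelled females correlated at 0.882, against 0.97 to 0.98 within the other groups, a wider spread that the simulation lacks. Only 176 tested genes were changed in the simulation of the genotype effect and 176 in that of the interaction, whereas 4132 and 978 passed in the real data. At a Benjamini-Hochberg threshold, the share found and the share of wrong calls depend on how many genes change. The percentages thus hold for groups of equal spread and for few changed genes. For the genotype effect (11972 simulated genes), 7.1% of genes changed 1.5-fold passed the threshold, 50% at 2-fold and 100% at 4-fold, and 10.9% of the calls were wrong, more than the nominal 5%. For the interaction (11963 genes), 0% passed at 2-fold, 55.6% at 4-fold and 86.7% at 8-fold, with 14.7% of calls wrong. At 4-fold, 84.8% passed within females, 86.7% within males, 84.4% between the sexes in WT and 91.1% in LKO livers, with 8.2%, 15.9%, 9.5% and 11.4% of calls wrong. In 40 simulated datasets with no change, 4.89% of genes had a genotype p under 0.05, and 1.3 genes on average passed. Small p-values were more frequent among genes under a mean FPKM of 2, where 0.291% had p under 0.001, than above it, where 0.077% did. Camera called 5 of 5 changed and 1 of 33 unchanged lists. These lists were random and their genes were drawn independently. The wrong calls of camera for lists whose members vary together were thus not measured. The autosome spread test gave p under 0.05 in 3 of those 40 datasets and the correlation of the parts in 2.

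Alternatives were a pseudocount of 0.1, no filter, a filter at a mean FPKM of 2, median-of-ratios scaling, quantile normalization, limma-voom on the recovered fragments, array weights, no sex term, and leaving out each library in turn. Chosen after seeing the data were a fit without the 2 libraries low in Gm42418, removal of each library's trend with transcript GC content and length (13507 genes with a value), totals without the 50 most abundant genes, the block on title numbers, and heptamer lists matched also on GC content. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.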

Results

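Liver RNA was compared between 4 WT and 4 LKO-labelled samples, each with 2 females and 2 males. The 4 WT libraries held 16.6, 17.0, 18.1 and 15.1 M fragments in females 1 and 2 and males 3 and 4. In the same order, the 4 LKO-labelled libraries held 15.6, 16.8, 18.8 and 17.8 M. Mitochondrial genes took between 6.52% and 7.75% of fragments in WT livers, 2.80% and 3.44% in the LKO-labelled females, and 7.08% and 10.4% in the LKO-labelled males. The 50 most abundant genes took 34.2% to 36.9% in WT livers, against 25.3% and 29.2% in the LKO-labelled females and 32.8% and 33.2% in the males. The number of genes with an FPKM of at least 1 was 10271 to 10849 in WT livers, 11135 and 11239 in LKO-labelled males, and 12667 and 12798 in LKO-labelled females. Gm42418, a predicted gene that overlaps ribosomal RNA sequence, took 0.06% of fragments in WT male 4 and 0.042% in LKO-labelled female 1, and 3.19% to 4.34% in the other 6 libraries, so these 2 libraries differed from the rest in a way that neither genotype nor sex follows.

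Correlations of log2 values across genes were 0.979 between the WT females, 0.98 between the WT males and 0.97 between the LKO-labelled males, and 0.882 between the LKO-labelled females. The first principal component held 54% of the variance. It placed the 4 WT libraries between −59.1 and −47.2, the LKO-labelled males at 11.4 and 15.3, and the LKO-labelled females at 102.2 and 78.5. The second component, with 22.1%, set the LKO-labelled males (68.3 and 59) apart from the other 6 libraries, which lay between −36.3 and −9.9.

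The targeted genes were measured first, since they check the labels. Zfp36 encodes tristetraprolin (ENSMUSG00000044786, chromosome 7, 28376784 to 28380253, minus strand, GRCm38). It fell from 44.5 ± 13.2 FPKM (SD, n = 4) in WT to 9.30 ± 6.48 FPKM (SD, n = 4) in LKO-labelled livers, or 20.9% of WT (two-sided exact permutation p = 0.0286, and 0.0556 with permutation within sex; limma log2 change −2.33 ± 0.43 SE, adjusted p 0.00722). Zfp36l1, which encodes a family member also called BRF1 (ENSMUSG00000021127, chromosome 12, 80107754 to 80113013, minus strand), went from 15.5 ± 4.95 to 3.62 ± 3.85 FPKM (SD, n = 4 each; exact permutation p = 0.0286, within sex 0.0556; log2 −2.21 ± 0.50 SE, limma adjusted p 0.0152). Zfp36l2, the third family member (ENSMUSG00000045817, chromosome 17, 84183931 to 84187947, minus strand), stood at 14.6 ± 2.23 FPKM in WT and 14.8 ± 13.8 FPKM in LKO-labelled livers (SD, n = 4 each; exact permutation p = 0.486, within sex 0.444; log2 −0.44 ± 0.49 SE, limma adjusted p 0.5). Within sex, 0.0556 is the smallest p that 36 assignments can give, so that test cannot pass 0.05.

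The mean of Zfp36l2 joined opposite values in the sexes. Its FPKM was 18.1 and 33.04 in the LKO-labelled females, above all 4 WT livers (11.8 to 17.2), and 4.34 and 3.86 in the males, below all of them. As a share of WT of the same sex, Zfp36 stood at 41.2% in LKO-labelled females and 7.6% in males, Zfp36l1 at 49.1% and 3.4%, and Zfp36l2 at 191.7% and 26%. The limma interaction, the female minus the male change, was 2.19 for Zfp36 (adjusted p 0.0267), 2.53 for Zfp36l1 (0.033) and 2.55 for Zfp36l2 (0.0212). By voom on recovered fragments, and without any 1 of the 4 WT livers, these 3 interaction calls ended, with the sign kept. An FPKM over a whole gene can include reads outside the deleted part, so a value above 0 does not give the share of cells that kept a gene. Zfp36l2 thus went against the label in both females, and the term LKO-labelled is kept for all directions given here.

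**Figure D1:**
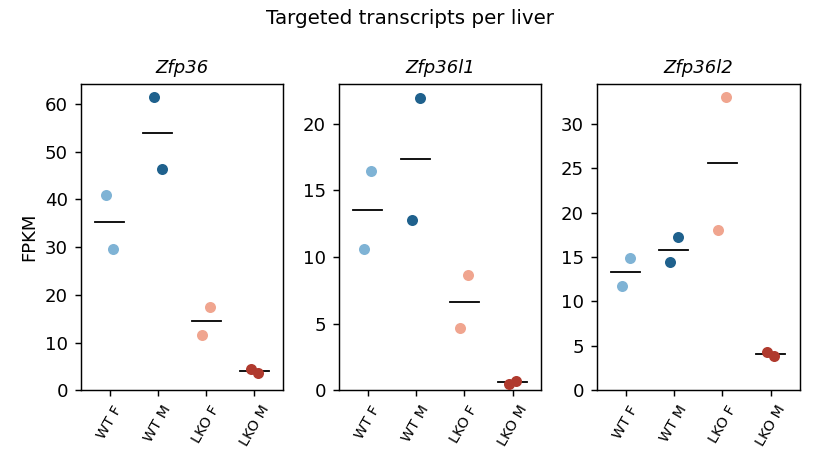
FPKM of Zfp36, Zfp36l1 and Zfp36l2 in each of the 8 livers, by genotype label and sex, with points for livers and a black bar for the mean of 2 livers. The LKO-labelled males lie below all WT livers for the 3 genes, at 0.4994 to 4.514 FPKM, whereas the LKO-labelled females reach 18.05 and 33.04 FPKM for Zfp36l2.

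The main comparison asked which genes differed between the genotype labels. Insulin-like growth factor 2, a fetal growth factor encoded by Igf2 (ENSMUSG00000048583, chromosome 7, 142650766 to 142666816), rose most among the named protein-coding genes, from 0.161 ± 0.126 to 954 ± 1430 FPKM (SD, n = 4 each; log2 7.43 ± 1.05 SE, limma adjusted p 0.00298). Trefoil factor 3 (Tff3), a mucosal repair peptide, rose from 0.414 ± 0.570 to 226 ± 153 FPKM (log2 7.17 ± 0.47 SE, adjusted p 0.000181), in every LKO-labelled liver above every WT liver. Fgf21, a liver hormone induced by fasting and stress, rose from 0.868 ± 0.331 to 301 ± 337 FPKM (6.57 ± 0.68 SE, adjusted p 0.000934). The secreted glutathione peroxidase Gpx3 rose from 3.51 ± 0.97 to 191 ± 121 FPKM (5.20 ± 0.29 SE, 9.95e-05), and lipoprotein lipase, Lpl, which is low in adult hepatocytes, from 4.03 ± 1.23 to 180 ± 65.0 FPKM (5.12 ± 0.32 SE, 0.000169). The other 7 of the 12 largest rises were Spink1 (log2 6.29), Igfbp1 (5.31), Lcn2 (5.30), Defb1 (5.17), Scd2 (5.08), Cbr3 (5.07) and S100g (5.03). Igfbp1, which binds insulin-like growth factors, reached 894 ± 582 FPKM from 20.8 ± 19.9.

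Cytochrome P450 2E1, a pericentral enzyme of alcohol and drug oxidation, fell most, from 4365 ± 392 to 120 ± 166 FPKM (Cyp2e1, ENSMUSG00000025479, chromosome 7, 140763739 to 140774987; SD, n = 4 each; log2 −6.22 ± 0.68 SE, limma adjusted p 0.00107). Cyp1a2 fell from 358 ± 54.1 to 7.94 ± 6.39 FPKM (−5.68 ± 0.55 SE, 0.000835). Ornithine aminotransferase, Oat, fell from 756 ± 212 to 23.9 ± 29.3 FPKM (−5.60 ± 0.60 SE, 0.000995). Carbonic anhydrase 3, Car3, fell from 1994 ± 997 to 53.9 ± 31.7 FPKM (−5.48 ± 0.59 SE, 0.00105). Further large falls were in genes with near-identical copies, whose single values are uncertain: Cyp2c50 (−5.65), Sult2a8 (−5.43), Mup15 (−5.28), Cyp2c37 (−4.91), Cyp2c54 (−4.63) and Mup3 (−4.61). Akr1c6 also fell (−4.63). Mup17 was listed at 0 in all 4 LKO-labelled livers, against 50.6 ± 32.3 FPKM in WT.

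In the genotype effect (Triple LKO against WT), 4132 of 13573 genes passed the limma threshold, 3353 higher and 779 lower, of which 1861 and 508 changed at least 2-fold. The median log2 change of all tested genes was 0.39, and 0.30 when totals were formed without the 50 most abundant genes, so changes of lists are to be read against that shift. The share of passing genes that were higher, 81.1%, was 48.9% after median-of-ratios scaling, 43.2% after quantile normalization, 42.5% after removal of trends with GC content and length, and 74.8% without the 50 most abundant genes. Without the 2 libraries low in Gm42418, 2102 genes passed and the call of Zfp36l1 ended. In a fit with livers paired by neighbouring title numbers, 2505 genes passed.

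For the gene lists, counts are given over all tested genes and then, in brackets, adjusted over the list alone, followed by the median log2 change and camera's adjusted p against all other genes. Of 38 lists, 25 passed, 8 up and 17 down, and 0 passed with an estimated correlation, whose adjusted p is given second. At an unadjusted camera p under 0.05 there were 26 lists, and fry called 16.

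Markers of fetal liver and liver tumours were higher as a group. Of 30 oncofetal genes, 22 were higher (25 adjusted over the list alone), with a median of 2.89 (8.77e-07, and 0.394 with an estimated correlation). Ly6d, a cell-surface marker, rose from 0.691 ± 0.723 to 39.0 ± 25.1 FPKM (SD, n = 4 each). H19, an imprinted RNA next to Igf2 (ENSMUSG00000000031, chromosome 7, 142575529 to 142578143), rose from 0.392 ± 0.502 to 696 ± 944 FPKM (log2 6.65 ± 1.11 SE, limma adjusted p 0.00517). Alpha-fetoprotein, Afp (ENSMUSG00000054932, chromosome 5, 90490737 to 90508907), had a log2 change of 5.60 ± 1.60 (SE, adjusted p 0.0314), and the cell-surface proteoglycan Gpc3 one of 3.19 ± 0.81 (0.0222). Both calls ended under several alternatives.

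Proliferation genes were higher in 33 of 36 cases (33 higher and 1 lower adjusted over the list alone), with a median of 1.76 (4.04e-09, and 0.41 with an estimated correlation). The replication helicase subunit Mcm6 went from 1.06 ± 0.230 to 12.1 ± 5.03 FPKM (log2 2.61 ± 0.27 SE, adjusted p 0.000963), and the microtubule regulator Stmn1 from 3.79 ± 1.36 to 28.8 ± 12.4 FPKM. The dividing-cell marker Mki67 stood at 3.72 ± 2.17 FPKM against 0.285 ± 0.240 (log2 1.78 ± 0.34 SE, 0.00856). Among 23 p53 targets, 15 were higher and 1 lower (18 and 1 adjusted over the list alone, median 1.09, camera 0.000767, and 0.153 with an estimated correlation). The cell-cycle inhibitor Cdkn1a rose from 4.01 ± 4.88 to 86.5 ± 28.7 FPKM (4.47 ± 0.49 SE, adjusted p 0.00107), and the p53 targets Phlda3 and Btg2 by 3.05 and 2.90 on the log2 scale. Myc had a log2 value of 1.01 ± 0.46 (SE, adjusted p 0.119), and cyclin D1, Ccnd1, one of −0.16 ± 0.51 (0.826).

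Of 21 Wnt and pericentral genes, 16 were lower (16 adjusted over the list alone, median −1.68, camera 1.03e-19, and 0.123 with an estimated correlation). The glutamate transporter Slc1a2 fell from 25.3 ± 5.65 to 0.278 ± 0.444 FPKM and the Wnt target Notum from 8.27 ± 2.81 to 0.379 ± 0.280 FPKM. Drug-metabolising P450s were lower in 10 of 22 cases (12 adjusted over the list alone, median −1.29, camera 1.78e-13, and 0.123 with an estimated correlation). Urea cycle and amino acid breakdown had 1 of 23 genes higher and 11 lower (1 and 12 adjusted over the list alone, median −1.38, camera 4.52e-13, and 0.213 with an estimated correlation), among them tyrosine aminotransferase, Tat, at 305 ± 132 FPKM against 895 ± 226. Among 28 bile acid genes, 2 were higher and 11 lower (2 and 13 adjusted over the list alone, median −0.86, camera 1.74e-10, and 0.136 with an estimated correlation). The rate-limiting Cyp7a1 fell from 46.5 ± 18.1 to 2.84 ± 3.67 FPKM (log2 −3.96 ± 0.58 SE, limma adjusted p 0.00328), and Cyp8b1 had a log2 value of −2.65 ± 1.09 (SE, 0.0918). The sterol hydroxylase Cyp27a1 and the uptake transporter Slco1b2 had log2 changes of −1.68 and −2.03.

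Fatty acid oxidation and PPAR alpha targets had 2 of 28 genes higher and 11 lower (2 and 11 adjusted over the list alone, median −0.62, camera 4.04e-09, and 0.154 with an estimated correlation). Cyp4a10, which has near-identical copies, fell from 221 ± 80.4 to 16.7 ± 4.80 FPKM. Of 21 genes of fatty acid and triglyceride synthesis, 6 were lower (6 adjusted over the list alone, median −0.80, camera 1.6e-07, and 0.133 with an estimated correlation), including the carboxylase Acacb at −2.17 and the desaturase Fads1 at −1.98. Cholesterol synthesis and uptake had 5 of 25 lower (4 adjusted over the list alone, median −0.26, camera 1.99e-05, and 0.394 with an estimated correlation), with Ebp at −1.98 and Idi1 at −1.50. Fasn and Cpt1a had log2 values of 0.10 and −0.20 (limma adjusted p 0.82 and 0.544).

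Hepatocyte transcription factors and secreted proteins included 7 of 27 that were lower (7 adjusted over the list alone, median −0.54, camera 2.89e-08, and 0.136 with an estimated correlation). Hnf4a, a master regulator of hepatocytes, went from 217 ± 38.1 to 125 ± 19.1 FPKM (log2 −0.79 ± 0.22 SE, adjusted p 0.0279, lost in 5 of the fits without a library), and the nuclear receptor Nr1i3 from 39.9 ± 11.6 to 8.75 ± 6.46 FPKM. Albumin, Alb, had 33859 ± 2279 FPKM in WT and 17719 ± 3018 in LKO-labelled livers (−0.95 ± 0.35 SE, 0.0715). Growth hormone axis genes were higher in 2 and lower in 5 of 12 cases (2 and 6 adjusted over the list alone, median −0.92, camera 0.000214, and 0.153 with an estimated correlation). Igf1 fell from 128 ± 31.4 to 17.0 ± 9.52 FPKM (−2.94 ± 0.32 SE, 0.00108), and its carrier Igfals from 66.7 ± 21.2 to 7.56 ± 2.15 FPKM. Glucose production had 2 of 14 higher and 2 lower (2 and 3 adjusted over the list alone, median −0.54, camera 0.00124, and 0.41 with an estimated correlation). Periportal genes had 5 of 19 higher and 4 lower (5 and 5 adjusted over the list alone, median −0.96, camera 0.000948, and 0.41 with an estimated correlation), with Apoa4 up from 16.8 ± 1.88 to 342 ± 289 FPKM. Quantile normalization ended both calls.

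Circadian clock genes had 3 of 17 lower (1 adjusted over the list alone, median −0.52, camera 8.16e-05, and 0.154 with an estimated correlation), with the repressor Ciart at 1.97 ± 0.702 FPKM against 12.1 ± 6.46. The nuclear genes of the respiratory chain had 2 of 27 lower (0 adjusted over the list alone) and a camera adjusted p of 0.0172 downward (0.607 with an estimated correlation), although their median of 0.10 and mean of 0.02 were above 0. Quantile normalization ended this call. Male-biased liver genes had 1 of 18 higher and 3 lower (1 and 2 adjusted over the list alone, median −1.49, camera 0.00011, and 0.515 with an estimated correlation), and female-biased genes 3 of 20 lower (0 adjusted over the list alone, median −1.46, camera 1.33e-05, and 0.515 with an estimated correlation). Of 5 sex chromosome transcripts, 0 passed by limma, and 0 at an unadjusted p under 0.05 (0 adjusted over the list alone, median −0.31, camera 0.0248, and 0.197 with an estimated correlation), and their camera call ended under several alternatives.

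Of 29 acute phase genes, 11 were higher and 3 lower (11 and 3 adjusted over the list alone, median 0.79, camera 0.655, and 0.756 with an estimated correlation). The iron-binding protein Lcn2 rose from 4.72 ± 1.68 to 397 ± 510 FPKM (log2 5.30 ± 0.62 SE, limma adjusted p 0.00134) and haptoglobin, Hp, from 1330 ± 251 to 4532 ± 1014 FPKM, whereas Saa1 had a log2 value of 0.04 ± 0.78 (SE, 0.972). That value joined opposite changes of Saa1, 2.05 ± 0.54 in females (SE, limma adjusted p 0.024) and −1.96 ± 0.54 in males (0.0455). Cytokines and chemokines had 13 of 30 higher and 3 lower (19 and 4 adjusted over the list alone, median 1.30, camera 0.091, and 0.753 with an estimated correlation), with Cxcl1 at 39.8 ± 28.4 FPKM against 3.99 ± 1.02 and Tnf at 1.16 ± 1.27 against 0.128 ± 0.104 (log2 0.77, adjusted p 0.0705). Within females 24 of the 30 were higher (median 2.26, camera 0.000165, and 0.127 with an estimated correlation). Within males 3 were higher and 3 lower (median 0.26, camera 0.993 downward, and 0.995 with an estimated correlation). Tnf had log2 values of 1.27 in females (limma adjusted p 0.0164) and 0.27 in males (0.593). Interferon response genes had 12 of 28 higher and 1 lower (13 and 1 adjusted over the list alone, median 0.83, camera 0.0985, and 0.675 with an estimated correlation), with Usp18 up by 2.93 and Ifit2 by 1.90. Immediate early genes were higher in 14 of 23 cases (15 adjusted over the list alone, median 1.34, camera 0.00305, and 0.526 with an estimated correlation), with Klf6 up by 2.56 and Ier3 by 2.76 (0.0126).

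NRF2 targets had 9 of 21 higher and 1 lower (11 and 1 adjusted over the list alone, median 1.40, camera 0.0857, and 0.734 with an estimated correlation), and camera gave 0.0327 for this list (list: NRF2 targets) with livers paired by title numbers. The unfolded protein and integrated stress response list had 10 of 28 higher and 1 lower (10 and 1 adjusted over the list alone, median 0.61, camera 0.322, and 0.81 with an estimated correlation), with the stress hormone Gdf15 up from 3.18 ± 2.12 to 114 ± 111 FPKM. The Notch pathway had 7 of 15 higher (9 adjusted over the list alone, median 0.95, camera 0.0344, and 0.675 with an estimated correlation). The receptor Notch1 went from 2.16 ± 0.516 to 5.06 ± 0.475 FPKM (log2 0.95 ± 0.17 SE, limma adjusted p 0.00618), a call that ended after quantile normalization and with trends removed, and the list's call ended under several alternatives. YAP/TEAD targets had 4 of 16 higher (3 adjusted over the list alone, median 0.76, camera 0.711, and 0.916 with an estimated correlation), among them Axl and Crim1, whose calls ended under several alternatives.

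Of 30 stellate cell and fibrosis genes, 13 were higher and 2 lower (21 and 2 adjusted over the list alone, median 1.58, camera 0.0172, and 0.734 with an estimated correlation), with the basement membrane collagens Col4a1 and Col4a2 up by 3.28 and 3.25 and Col1a1 by 3.91 ± 0.89 (SE, limma adjusted p 0.0151). The list's call ended with array weights, without the sex term and without LKO-labelled female 1 or 2. Sinusoidal endothelium had 3 of 18 higher and 6 lower (4 and 7 adjusted over the list alone, median −0.32, camera 0.00105, and 0.526 with an estimated correlation), with Emcn up by 1.70 and Ptprb at −1.01. Stab2 had a value of −0.50 (0.198). Of 11 genes listed for adipocytes, 5 were tested and 4 were higher (5 adjusted over the list alone, median 2.13, camera 0.00285, and 0.146 with an estimated correlation), among them Lpl and the fatty acid carrier Fabp4, at 242 ± 173 FPKM against 10.6 ± 2.6. The other 6, Adipoq, Plin1, Lep, Retn, Cfd and Cidea, had means over the 8 livers of at most 0.3375 FPKM and were too low to test, so a rise of adipocytes does not follow from the 5. Macrophage genes had 11 of 25 higher and 5 lower (14 and 6 adjusted over the list alone, median 1.07, camera 0.892, and 0.966 with an estimated correlation). The resident Kupffer cell receptor Timd4 fell from 3.33 ± 1.33 to 0.240 ± 0.336 FPKM, while the Fc receptor Fcgr1 rose from 1.29 ± 0.587 to 5.88 ± 3.86 FPKM and Adgre1 had a log2 value of 0.56 (0.105). By sex, Adgre1 had 0.98 in females (limma adjusted p 0.0298) and 0.15 in males (0.757).

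Neutrophil genes had 7 of 12 higher (7 adjusted over the list alone, median 1.36, camera 0.0913, and 0.734 with an estimated correlation), with S100a9 at 59.9 ± 91.2 FPKM against 1.16 ± 0.379. Cholangiocyte and ductular genes had 3 of 13 higher (3 adjusted over the list alone, median 0.88, camera 0.211, and 0.734 with an estimated correlation), including Bicc1 and Elf3. Krt19 was too low to test, with a mean of 0.234 FPKM. T and natural killer cells had 1 of 17 higher, Cd27 (0 adjusted over the list alone, median 0.66, camera 0.257, and 0.797 with an estimated correlation), a call that ended under most alternatives, and Cd8a had a log2 value of 0.64 (limma adjusted p 0.178). Within females this list had 13 of 17 higher (14 adjusted over the list alone, median 1.34, camera 0.00146, and 0.413 with an estimated correlation). Within males it had 0 of 17 past (0 adjusted over the list alone, median −0.025, camera 0.16 downward, and 0.766 with an estimated correlation). B and plasma cell genes had 0 of 11 past, and 0 at an unadjusted limma p under 0.05 (0 adjusted over the list alone, 0.478 downward, and 0.834 with an estimated correlation), with a median of 0.26 and a mean of 0.18. Erythroid genes had 0 of 7 past, likewise 0 unadjusted (0 adjusted over the list alone, 0.392 downward, and 0.767 with an estimated correlation), with a median of 0.74 and a mean of 0.40.

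Reported targets of AU-rich element decay bear most directly on the family's known role. Of 45, 25 were higher and 1 lower (30 and 1 adjusted over the list alone, median 1.06, camera 0.00124, and 0.526 with an estimated correlation). In females 30 were higher and 1 lower (32 and 1 adjusted over the list alone, median 1.72, camera 1.54e-05, and 0.127 with an estimated correlation). In males, where the targeted transcripts were lowest, 7 were higher and 1 lower (7 and 1 adjusted over the list alone, median 0.58, camera 0.132, and 0.524 with an estimated correlation). The female minus the male change of this list had a median of 1.04, with 7 of 45 genes past (16 adjusted over the list alone, camera 5.49e-05, and 0.192 with an estimated correlation), and females were the sex with less loss of the 3 transcripts. The list of other AU-rich element binding and decay proteins had 6 of 24 higher (5 adjusted over the list alone, median 0.40, camera 0.0551, and 0.394 with an estimated correlation), with Tia1 up by 1.22 and Elavl1 by 1.09. Among 12291 tested genes with an annotated 3′ UTR, the 469 with at least 3 TATTTAT heptamers had a median log2 change of 0.46, against 0.40 for matched lists, at percentile 99.16. Heptamers TTAATTT and ATATTTT, tested as controls, gave percentiles of 17.59 and 61.49. The percentile of the TATTTAT genes was 43.31 in females and 99.84 in males.

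The interaction asked whether the genotype effect differed between the sexes, and 978 genes passed, 743 with a higher log2 change in females and 235 with a higher one in males. The 76% with a higher change in females were 61.5% after median-of-ratios scaling, 52.1% after quantile normalization and 50.9% with trends removed (genotype-by-sex interaction). Afp stood at 9159 and 1203 FPKM in the LKO-labelled females and at 1.43 and 7.88 in the males, so its change was larger in females by 8.60 ± 1.30 (log2, SE, limma adjusted p 0.0165). Igf2 reached 3044 and 719 FPKM in the females and 18.2 and 36.8 in the males (5.63 ± 0.88 SE, 0.0188). The neighbouring H19 went the other way, with 8.76 and 21.0 FPKM in the females and 736 and 2016 in the males (−6.05 ± 0.82 SE, 0.0138). The secreted matrix protein Spp1 was at 291 and 3145 FPKM in the females and 8.65 and 5.55 in the males (6.82 ± 1.29 SE, 0.0288), and Col1a1 at 79.2 and 320 against 2.69 and 2.55 (4.65 ± 0.82 SE, 0.0234). Timp1, an inhibitor of matrix proteases on chromosome X, was at 62.0 and 56.7 FPKM in the LKO-labelled females and 0.42 and 0.70 in the males (5.23 ± 0.29 SE, 0.000581).

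Among the genes with the smallest p were Sult3a1, Hsd3b5, Timp1, Mup7 and Sult2a2, of which all but Timp1 also differed between the sexes in WT. The female sulfotransferase Sult3a1 went from 163 to 0.0285 FPKM in females (means of 2), and the male steroid enzyme Hsd3b5 from 105 to 0.0332 in males. A gene near 0 in WT livers of 1 sex can fall only in the other. For such genes a fall alone gives an interaction. By voom on recovered fragments, 23 genes passed the interaction, and 569 did with livers paired by title numbers. Of the genes named here, Sult2a2 kept its call under every alternative. Those of Hsd3b5, Mup7, Sult3a1 and Timp1 ended by voom, and those of Afp, Igf2, H19, Spp1 and Col1a1 ended by voom and without any 1 of the 4 WT livers, with the sign kept. The number for the genotype-by-sex interaction ranged from 33 to 2694 with single libraries left out. It was 33 to 57 without any 1 of the WT livers or LKO-labelled male 3, 154 without LKO-labelled male 4, and 2400 and 2694 without LKO-labelled female 1 and 2.

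By camera, 22 of 38 lists differed between the sexes in their genotype effect, 13 with a higher and 9 with a lower value in females, 0 with an estimated correlation and 15 by fry. Stellate cell and fibrosis genes differed by a median of 2.81 (21 of 30 genes, 26 adjusted over the list alone, camera 1.85e-14, and 0.276 with an estimated correlation). Urea cycle genes differed by −2.09 (7 of 23, 17 adjusted over the list alone, camera 5.57e-12, and 0.176 with an estimated correlation), and cytokines by 1.66 (10 of 30, 18 adjusted over the list alone, camera 2.36e-07, and 0.131 with an estimated correlation). Proliferation genes differed by −0.46 (0 of 36, 1 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera 0.000457, and 0.71 with an estimated correlation).

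**Figure D2:**
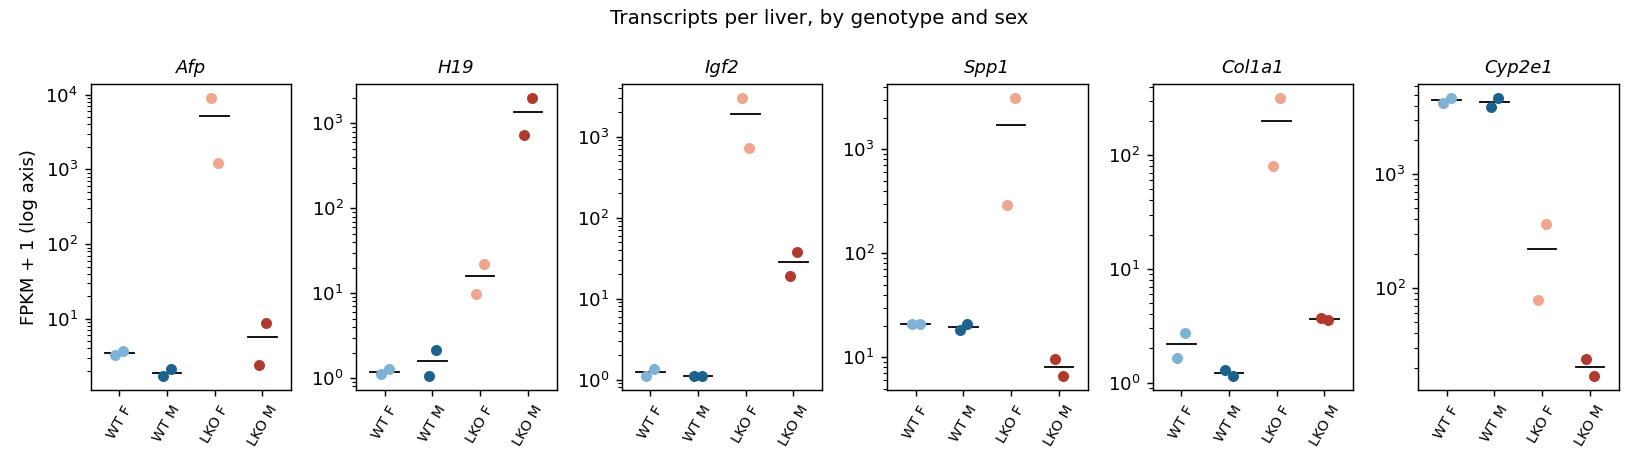
FPKM + 1 on a log axis for Afp, H19, Igf2, Spp1, Col1a1 and Cyp2e1 in each of the 8 livers, by genotype label and sex, with 1 point per liver. Afp reaches 9159 and 1203 FPKM in the LKO-labelled females and 1.43 and 7.88 in the males, while H19 reaches 736 and 2016 in the males.

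Within females, 4657 genes passed, 3812 higher and 845 lower, and within males 2374, 1819 higher and 555 lower. The shared spread is too narrow for the LKO-labelled females, which correlated at 0.882, and too wide for the males, at 0.97. These 2 counts are thus not a like comparison, and array weights raised that in males, as given below. For the genotype effect in females, the 81.9% that were higher were 55.9%, 48.2% and 48.0% after median-of-ratios scaling, quantile normalization and removal of trends. For the genotype effect in males, 76.6% became 52.7%, 53% and 53.1%. Igf2 rose by 10.25 ± 0.62 in females and by 4.62 ± 0.62 in males (log2, SE, limma adjusted p 0.000161 and 0.00502). Cyp2e1 fell in both sexes, to 77.3 and 365 FPKM in the LKO-labelled females and to 23.0 and 15.8 in the males. Higher in both sexes were 872 genes, against 510.9 for independent lists, lower in both 295, against 34.6, and 48 passed in opposite directions. Both contrasts share each gene's spread from 1 fit, and both carry an upward shift of all genes. The lists could thus not be independent, and 510.9 and 34.6 do not measure agreement between the sexes. The changes correlated across genes, which are not independent replicates, with r = 0.472 and rho = 0.404. Of the 978 interaction genes, 805 also passed in females and 300 in males. The median of all genes was 0.45 in females and 0.24 in males.

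In females, 28 lists passed by camera (0 with an estimated correlation, 26 by fry), led by urea cycle genes (median −2.11, 19 of 23 lower, 22 adjusted over the list alone, camera 1.02e-20, and 0.0797 with an estimated correlation) and female-biased genes (−4.29, 16 of 20 lower, 16 adjusted over the list alone, camera 1.43e-20, and 0.0509 with an estimated correlation). Stellate genes had a median of 3.10 in females (26 of 30 higher and 1 lower, 26 and 1 adjusted over the list alone, camera 3e-09, and 0.246 with an estimated correlation) and 0.21 in males (4 and 1, 4 and 1 adjusted over the list alone, camera 0.953, and 0.995 with an estimated correlation). Cholesterol genes in females had a median of 0.16 while camera's direction was down (0.00753, 1 of 25 higher and 4 lower, 0 and 3 adjusted over the list alone, 0.492 with an estimated correlation). In males, 16 lists passed (0 with an estimated correlation, 15 by fry), led by Wnt and pericentral genes (−1.76, 15 of 21 lower, 16 adjusted over the list alone, camera 2.67e-17, and 0.176 with an estimated correlation), male-biased genes (−3.65, 11 of 18 lower, 14 adjusted over the list alone, camera 2.27e-15, and 0.144 with an estimated correlation) and proliferation (1.90, 29 of 36 higher, 32 higher and 1 lower adjusted over the list alone, camera 8.29e-11, and 0.42 with an estimated correlation). Counts for the genotype effect in males moved by more than 1.5 times without any of the 8 livers, between 346 without WT male 3 and 4212 without LKO-labelled female 1.

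**Figure D3:**
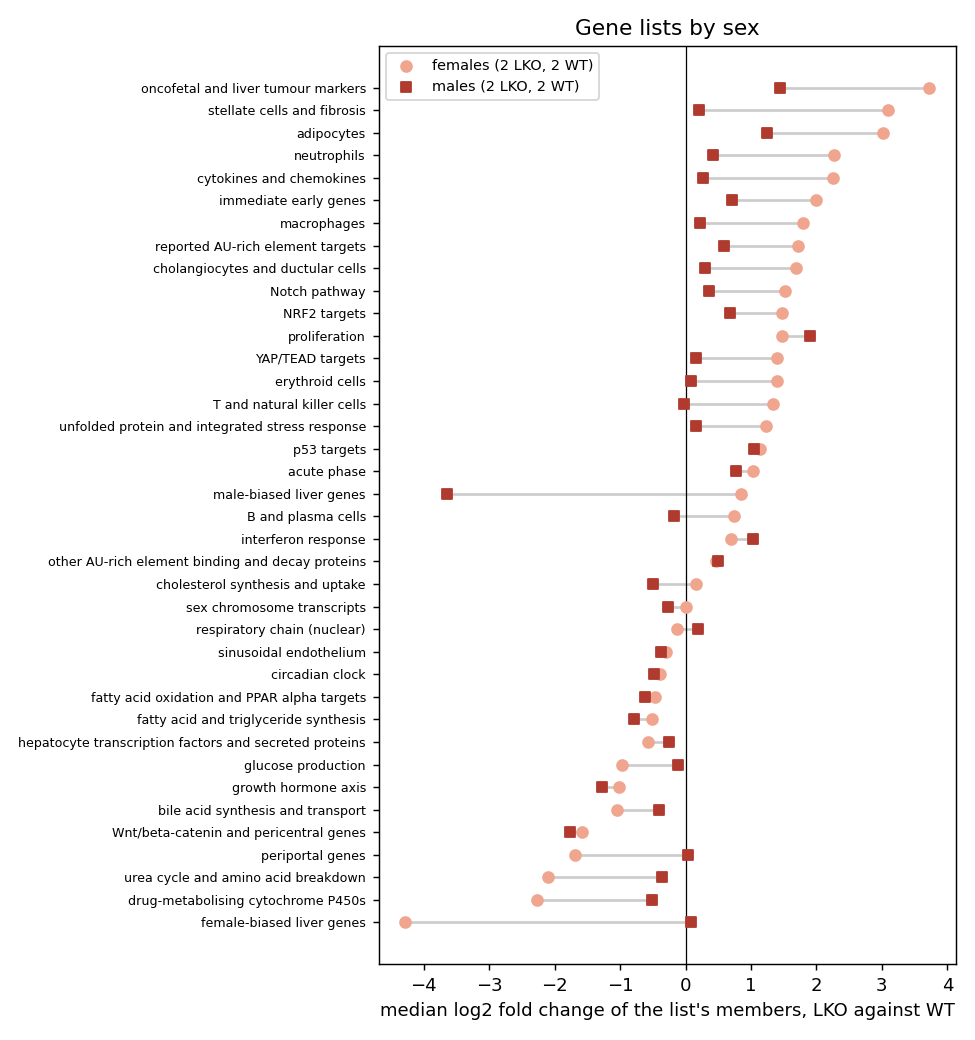
Median log2 change, LKO-labelled minus WT, of each tested gene list in females (circles) and in males (squares). The stellate list has medians of 3.10 in females and 0.21 in males, and the Wnt and pericentral list −1.59 and −1.76.

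Between WT males and females, which asked for the usual sex difference of mouse liver, 58 genes passed, 31 higher in males and 27 higher in females. Highest in males were Mup7 (730 FPKM in males, 0.0576 in females, means of 2; log2 9.33, limma adjusted p 9.85e-05), Serpina1e, Cyp2d9, Mup20 and Hsd3b5. Among the highest in females were A1bg (668 against 0.0667 FPKM; −8.90, 0.000935), Sult2a1, Cyp2c69 and Sult2a2. Mup, Sult2a, Serpina1, Cyp2c and Cyp2d genes have near-identical copies. The male-biased list had a median of 4.33 (10 of 18 higher in males, 17 adjusted over the list alone, camera 3.98e-62, and 0.0064 with an estimated correlation) and the female-biased list −6.24 (12 of 20 lower in males, 20 adjusted over the list alone, camera 1.26e-59, and 0.0064 with an estimated correlation). Camera called 15 of 38 lists, 2 with an estimated correlation and 2 by fry.

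Between LKO-labelled males and females, 3584 genes passed, 913 higher in males and 2671 higher in females. The shared spread of the model joins LKO-labelled females, which correlated at 0.882, with groups at 0.97 to 0.98. This count and the 58 in WT are thus not a like comparison. Array weights lowered this count and raised that in WT, as given below. For the sex difference in Triple LKO, the 25.5% that were higher in males were 45.0%, 52.7% and 53.6% under the same 3 changes of scale. The male-biased list had a median of −0.05 (4 of 18 higher and 1 lower in males, 4 and 1 adjusted over the list alone, camera 0.0667, and 0.436 with an estimated correlation) and the female-biased list one of −0.25 (4 of 20 higher in males, 4 adjusted over the list alone, camera 0.322, and 0.706 with an estimated correlation). H19 (log2 6.38, limma adjusted p 0.00085), Mup20 (4.66), Cyp2b10 (4.50) and Cyp2c38 (4.22) were among the highest in males. Afp (−9.48, 0.001), the immunoglobulin genes Igkc (−7.59) and Ighm (−6.22), Spp1 (−6.91) and Igf2 (−5.78) were highest in females. Camera called 21 of 38 lists, 0 with an estimated correlation and 17 by fry. For the sex difference in Triple LKO, the count without LKO-labelled male 3 was 1396 and without male 4 it was 2028.

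Medians of whole autosomes were set against the WT livers for each library over 9983 genes. In LKO-labelled female 1, chromosome 15 stood at 0.66, chromosome 18 at 0.57, chromosome 16 at 0.55, chromosome 19 at 0.47 and chromosome 6 at 0.42, whereas chromosome 13 stood at −0.49, chromosomes 4 and 12 at −0.41, chromosome 10 at −0.39, chromosome 14 at −0.37 and chromosome 3 at −0.33 (log2 after the library's own median). Their SD over 19 autosomes was 0.37, against 0.047 for shuffled genes (permutation p 1e-04, the smallest possible). Shuffling also gave p of 3e-04 for WT female 1 and 0.0456 for WT male 4, at SDs of 0.023 and 0.019, so a small p alone does not set a library apart from WT. The proximal and distal parts of the chromosomes shifted together, with r = 0.89 (permutation p 1e-05, the smallest possible; 8e-05 adjusted over 8 libraries) and rho = 0.83 (permutation p 2e-05), and r = 0.9 without the 2 farthest chromosomes. The SD was 0.019 to 0.023 in the WT livers, 0.067 in LKO-labelled female 2, and 0.093 and 0.098 in the LKO-labelled males 3 and 4. In male 4, chromosome 10 stood at −0.23 and chromosome 15 at 0.17, with r = 0.75 between the parts (permutation p 6e-05, adjusted 0.00024). In male 3 these 2 chromosomes stood at −0.19 and 0.12, the same direction as in female 1, and in female 2 at 0.01 and 0.08. Chromosomes 6 and 19, raised in female 1, stood at −0.13 and −0.16 in male 3 and at −0.05 and −0.06 in male 4. The parts gave r = 0.34 in male 3 (adjusted 0.421) and 0.22 in female 2 (0.563). Without the 2 farthest chromosomes, r was 0.62 in male 4, 0.6 in male 3 and −0.19 in female 2.

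**Figure D4:**
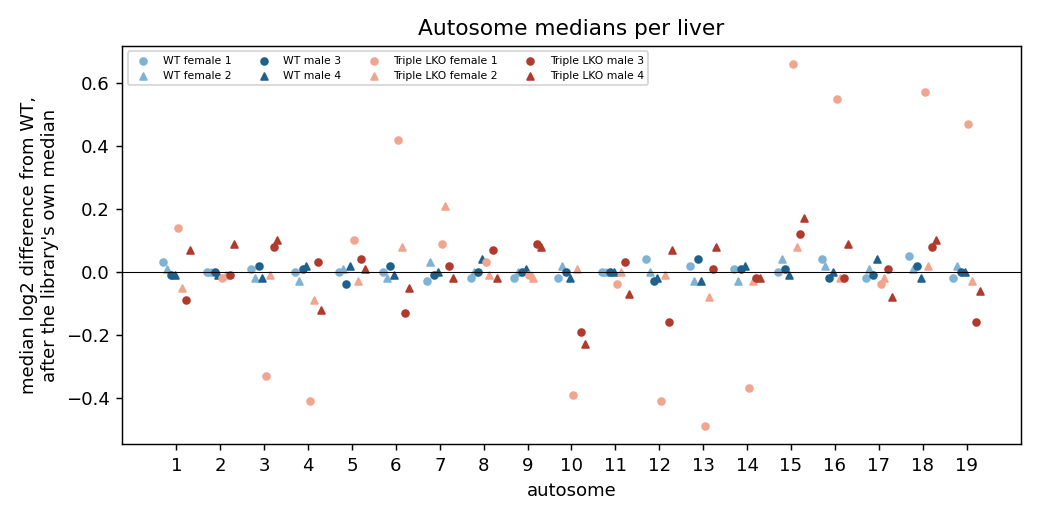
Median log2 difference from WT livers, after the library's own median, of each of the 19 autosomes in each of the 8 livers, with 1 point per autosome. The medians of LKO-labelled female 1 spread from −0.49 (chromosome 13) to 0.66 (chromosome 15), and the SD in WT livers is at most 0.023.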

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

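The tests of lists of other cells against each other, of lists of hepatocyte genes against each other, of RNA from other cells and of whole-chromosome gains and losses were chosen only after the results they address were seen, and so was the percentile rule for the heptamers.

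In 15 of 112 groups of 4 livers of 1 genotype, a single library lay far from the other 3. The rule marks about 1 in 20 groups when all 4 values are normally distributed and come from 1 population. These groups join females and males, and a group such as Spink1 in WT, at 0 in the other 3 livers, meets the rule at any distance. The rate by chance is thus not known here, and whether 15 exceeds it was not tested. Among WT livers, these were female 1 for S100g (0.1254 FPKM) and Mup17 (2.403), female 2 for Igf2 (0.3489), male 3 for Igfbp1 (50.36), Cdkn1a (11.34), Spp1 (17.45) and the share of the 50 most abundant genes (36.89%), and male 4 for Spink1 (0.3137). Among LKO-labelled livers, they were female 1 for Scd2 (339.3), Car3 (6.43) and Afp (9159), and female 2 for Cyp2c50 (32.43), Mup15 (0.5157), Akr1c6 (79.96) and Spp1 (3145). The 7 values from LKO-labelled livers were all from females, and the WT values of Igf2, Spink1 and S100g were near 0.

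A different genotype effect in females and males stood out for 13 single genes, as the female minus the male log2 change: Zfp36 2.19, Zfp36l1 2.53, Zfp36l2 2.55, Igf2 5.63, Spink1 3.20, Ier3 3.13, Afp 8.60, Gpc3 4.15, H19 −6.05, Saa1 4.01, Col1a1 4.65, Spp1 6.82 and Cd8a 1.70. Limma's adjusted p lay between 0.011 and 0.033 for these. All 13 calls ended by voom and without any 1 of the 4 WT livers, with the sign kept.

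By camera the same held for 22 lists, given by the median difference. Higher in females were AU-rich element targets (1.04), oncofetal markers (1.59), cytokines (1.66), stellate cells (2.81), cholangiocytes (1.52), macrophages (1.20), T and natural killer cells (1.31), neutrophils (1.89), male-biased genes (3.53), the unfolded protein response (0.72), Notch (1.01), YAP/TEAD (1.33) and immediate early genes (1.13). Lower in females were proliferation (−0.46), bile acids (−0.75), hepatocyte factors (−0.50), the urea cycle (−2.09), glucose production (−0.90), P450s (−0.89), female-biased genes (−5.32), periportal genes (−1.78) and the respiratory chain (−0.42). For the sex-biased lists the difference came mainly from 1 sex. Male-biased genes had medians of 0.85 within females and −3.65 within males, and female-biased genes −4.29 and 0.09. With an estimated correlation, 0 of the 22 passed.

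The first pattern is that genotype effects differed between the sexes. After removal of each library's trend with GC content and length, 806 genes still passed the genotype-by-sex interaction, 638 of them among the 978, which argues against those trends as the whole cause. A lower share of hepatocytes would raise all other cell types alike, but the interaction medians, the female minus the male change, of 7 lists of other cells (126 genes) had an SD of 0.84, against 0.35 for genes shuffled over the lists (permutation p 3e-04). Their medians were 2.81 for stellate cells, 1.89 for neutrophils, 1.52 for cholangiocytes, 1.31 for T and natural killer cells, 1.20 for macrophages, 1.01 for B cells and 0.05 for endothelium. In endothelium 9 of 18 genes were above 0, and the list means of the LKO-labelled females lay apart (−0.586 and 0.724 from WT). An earlier version of this test compared only stellate cells and endothelium, the extremes (difference 2.76, permutation p 1e-05). A lower share of hepatocytes can still be part of the cause, since 6 of the 7 medians were at least 1.01. Dilution of hepatocytes would lower their genes alike, but the interaction medians of 7 lists of hepatocyte genes (135 genes) had an SD of 0.80, against 0.37 for genes shuffled over the lists (permutation p 0.002). A first version of this test held 10 lists, 3 of them of lipid functions that other cells share, and gave an SD of 0.96 (permutation p 1e-04). The 7 medians ran from −2.26 for the urea cycle and −1.82 for periportal to 0.12 for pericentral genes. All but that of pericentral genes were below 0, so dilution can still be part of the cause. P450s (−0.89) and secreted proteins and factors (−0.50) alone gave a permutation p of 0.319. These permutations treat genes as independent. How many of the 978 genes stood near 0 in WT livers of 1 sex, and so could fall only in the other, was not counted. Sex itself, age, tumour content and a different extent of gene loss in the 2 females stay open, as untested, and by voom (23 genes) and without single libraries (33 to 2694) the count changed widely.

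The second pattern is that the targeted transcripts were higher in LKO-labelled females than in males, by 1.59 for Zfp36, 2.21 for Zfp36l1 and 2.32 for Zfp36l2 (log2 of FPKM + 1). That scale narrows differences at low values, as for Zfp36l1, which averaged 6.65 FPKM in the females and 0.597 in the males. Which lists reach a transcript thus depends on the scale. More RNA from cells that keep the 3 genes may explain the higher values in females. On this scale, for 3 of the 3 transcripts the median of a list of other cells was as much higher in females. Only the stellate list (3.21) reached all 3, against 2.09 for neutrophils, 1.78 for macrophages, 1.77 for T and natural killer cells, 1.64 for B cells, 1.45 for cholangiocytes and 0.62 for endothelium. This test is lenient, because a rise of a list does not give the amount of these transcripts that its cells bring. Zfp36 (11.64 and 17.4 FPKM) and Zfp36l1 (4.667 and 8.632) in both LKO-labelled females lay below every WT liver (at least 29.52 and 10.61), and the first principal component set these females farthest from WT (102.2 and 78.5), which goes against their being WT livers under a wrong label. Incomplete deletion in hepatocytes, a liver of another genotype and a difference between the sexes were not tested and stay open.

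The third pattern is the shift of whole chromosomes in LKO-labelled female 1. Removal of its trend with GC content and length left r = 0.92 between the parts of the chromosomes, and clusters of co-regulated neighbours would not give the r of 0.89 seen as deposited between proximal and distal parts. Gains and losses of whole chromosomes in a large share of the cells may be the cause, as the SD of the medians was 0.37 against at most 0.023 in WT livers, and the parts shifted together. The parts were alike on some chromosomes, such as 13 (−0.48 and −0.49) and 18 (0.60 and 0.55). On others they differed, such as 4 (−0.62 and −0.20) and 7 (0.21 and −0.03). Shifts of parts of chromosomes are thus not told apart from shifts of whole ones. Whether DNA copy number changed cannot be read from RNA, and the labels do not give tumour content. Without this library 3602 genes passed the genotype effect (Triple LKO against WT), 3219 of them shared with the 4132.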

How the results depend on the processing

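No label pairs the livers, and replicate numbers follow sample order. With livers paired by neighbouring title numbers, a block chosen after seeing the data, 2505 genes passed the genotype effect (Triple LKO against WT), 569 the genotype-by-sex interaction, 4561 the genotype effect in females and 2105 that in males, with 26 gene lists. Of the named genes, 121 of 131 kept direction and side of the threshold, while Afp, Gpc3, Hnf4a, Cd27, Cyp2b13, Sult3a1, Sdha and Uqcrb lost and Cyp8b1 gained a call for genotype, and Cd8a lost that for the interaction.

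Genes near an FPKM of 0.5 rest on few fragments. With 2 livers per genotype and sex, 0% of 2-fold interactions passed in the simulation, in which few genes changed. A fit that leaves out 1 library leaves 1 liver in a cell, which is assumed to vary like the others. Of the named genes, between 126 of 156 (without WT 1) and 145 of 146 (filter at a mean FPKM of 2) kept direction and side of the threshold per setting, 129 of 156 by voom and 104 of 113 without the sex term. The 13 single genes with a different effect in females and males lost that call by voom and without any WT liver. Where no construction explains a change, the cause was not tested. Without the 2 libraries low in Gm42418, with trends removed, with other totals and the block are settings chosen after seeing the data.

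The count of genes for the genotype effect (Triple LKO against WT), 4132, was 2421 after quantile normalization, 2102 without the 2 libraries low in Gm42418, 2608 with GC and length trends removed, and 1946 to 4068 with single libraries left out (2345 without WT 1, 1946 without WT 2, 2461 without WT 3, 2747 without LKO 4). The genotype-by-sex interaction, 978, was 577 with a pseudocount of 0.1, 604 without filter, 23 by voom and 33 to 2694 with single libraries left out, moved by each of the 8; removing the 2 libraries gave 1419 and trend removal 806. The genotype effect in females, 4657, ranged from 2028 to 5801 (2029 without WT 1, 2028 without WT 2). The genotype effect in males, 2374, was 1574 without filter, 1559 after quantile normalization, 4109 with array weights and 346 to 4212 with single libraries left out. The sex difference in WT, 58, was 32 without filter, 29 by voom, 161 with array weights and 30 to 101. The sex difference in Triple LKO, 3584, was 2018 with array weights and 1396 to 4509. The fixed gene lists, 25, were 0 with an estimated correlation, 16 by fry and 22 to 27 with single libraries left out.

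Values that changed sign were as follows, in log2. After median-of-ratios scaling Fasn was −0.33 and Saa1 −0.39, after quantile normalization Saa1 −0.12, and with array weights Ccnd1 0.63, Cpt1a 0.02, Saa1 −1.37 and Spp1 −0.03. Without the 2 libraries low in Gm42418 Ccnd1 was 0.37 and Saa1 −0.53, with trends removed Fasn −0.43 and Saa1 −0.40, and with other totals Fasn −0.01 and Saa1 −0.07. With single libraries left out, Ccnd1 ranged from −0.64 to 0.27, Fasn from −0.21 to 0.42 and Saa1 from −0.66 to 0.65.

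Lists that changed direction, with camera's or fry's adjusted p, were as follows. The list: B and plasma cells (fry 0.621, median-of-ratios 0.878, without the 2 libraries 0.658) was 1 of them, with erythroid cells (fry 0.716, quantile 0.918), the respiratory chain (nuclear) (fry 0.947), macrophages (array weights 0.724, no sex term 0.572, 0.298 to 0.985 with single libraries left out, turning without WT 1 or 2 or LKO 1 or 2), T and natural killer cells (array weights 0.729) and YAP/TEAD targets (array weights 0.675, 0.199 to 0.982, turning without WT 2 or LKO 2).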

Other observations

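The imprinted genes Peg3, Meg3 and Rian were chosen after their values were seen. Peg3 stood at 121 and 26.9 FPKM in LKO-labelled females 1 and 2, 2.247 and 4.535 in LKO-labelled males and 0.3503 to 1.170 in WT livers. The RNAs Meg3 and Rian stood at 22.4 and 41.2 FPKM in LKO-labelled female 1, 1.230 and 1.106 in female 2, at most 0.06241 in the LKO-labelled males and at most 0.7643 in WT livers. The pancreatic protease gene Try5 stood at 61.5 FPKM in LKO-labelled female 1 and was listed at 0 in the other 7 livers. Cela1 stood at 101 FPKM there, at 6.823 to 35.14 in WT livers and at 15.14 to 30.98 in the other LKO-labelled livers. Other acinar genes, Cpa1, Pnlip, Ctrb1 and Amy2a5, were listed at 0 in all 8. The list of acinar cells had 3 of 13 members tested and was not put to a test. The Y-linked helicase Ddx3y was at 18.2 and 16.0 FPKM in WT males and at 8.39 and 1.13 in LKO-labelled males (log2 −2.01, limma adjusted p 0.0525). The Y-linked Kdm5d stood at 1.308 and 2.574 FPKM in LKO-labelled males 3 and 4 (WT males 2.632 and 2.316) and Eif2s3y at 9.315 and 17.69 (19.70 and 21.57), so both were lower with Ddx3y in male 3 and near WT in male 4. The immunoglobulin gene Igkc was at 792 FPKM in WT female 2 and 35.04 in WT female 1.

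Of 35 ways to split the 8 livers into 4 and 4, only the split by genotype, 1 of 35, gave as many genes as 4132. The highest of the others gave 2 genes. A share of 1 of 35 is the smallest that 35 splits can give, and splits that mix the genotypes widen the spread within each side. The count by genotype thus stood apart from the other splits, but chance is not excluded. For the gene lists the split by genotype did not stand apart, since 7 of the 35 splits gave at least 25 lists, and the highest of the others gave 30. For the heptamers, 2 of the 35 splits lay as far from matched lists as the real one, at 0.0619, and the highest other at 0.0743, so chance is not excluded.

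The hypothesis that loss of mRNA decay through TATTTAT heptamers raised their genes was tested by the percentile of their median, 99.16. The rule at first counted a high percentile as a fit, and was changed after the values were seen because of the splits, so these data cannot tell. With at least 1 heptamer the percentile was 100, with at least 1 nonamer 99.9, and with lists matched also on GC content 99.98. Camera, which is not a permutation test, gave an unadjusted p of 0.48 and 0.786 with an estimated correlation, and the percentile was 43.31 in females and 99.84 in males.

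The candidate source of RNA named for the targeted transcripts rests on lists written before the tests. Of the 30 stellate genes, 18 had a WT mean of at least 1 FPKM, so whole liver also expresses them, and 1 is in another list. In the LKO-labelled females, Col1a1 averaged 199 FPKM and Col4a1 127 FPKM (means of 2). For macrophages, 17 of 25 genes had a WT mean of at least 1 FPKM and 0 were in another list, and for endothelium 16 of 18 and 0. For T and natural killer cells the numbers were 3 of 17 and 1, for B cells 5 of 11 and 0, for neutrophils 2 of 12 and 0, and for cholangiocytes 6 of 13 and 2. Of the 22 P450 genes and the 27 hepatocyte genes, 6 each are also in other lists. For the AU-rich element targets, 24 of the listed genes are in another list, so their rise is not wholly separate from that of other lists. The stellate list was the only one that reached 3 of 3 targeted transcripts on the scale log2(FPKM + 1). That rule was chosen after the values were seen, and the rise of a list does not give the amount of these transcripts its cells bring. Whether RNA from stellate cells underlies the female values is thus not decided. Measuring the 3 genes in sorted hepatocytes would test it.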
